A study of Arabidopsis thaliana with 6 samples.

How the data were processed

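Total RNA from seedlings of the accession Col-0 and the mutant naa20-1 was measured on 1 array per sample, with 3 samples per genotype. Per the labels' protocols the seedlings were 17 days old and grew on MS medium of 1x strength in short days of 8.5 h light at 100 µE, and biotin-labelled cRNA was hybridised by the standard Affymetrix procedure. The deposited table holds log2 expression values made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, equalises the distributions of the arrays by quantiles and summarises the probes of a probe set into 1 value. The array type, the probe set definition and the software are not given in the sources used here. The table gives no detection calls, so a dim value may be background.

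The table held 27827 probe sets, each carrying an Arabidopsis locus code, with 1 probe set per locus. Values ran from 1.75 to 14.58, with a median of 6.12 on every array. The sorted values of 5 arrays were identical, and those of naa20-1 replicate 1 departed from them by at most 0.0019 and held more distinct values (27643 against 10229). The reason is not given in the sources used here. Pearson correlations between arrays, taken across probe sets, were 0.993 to 0.995 within a group and 0.990 to 0.993 between groups, and no array repeated another (at most 0.370% of probe sets held the same value in any pair). For arrays, depth is not counted in reads, and their number limits the precision.

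Locus codes were matched to the reference gene table of assembly TAIR10.1, which was used for names and for the order of neighbouring genes only. The match took in 27241 probe sets, of which 26486 were of protein-coding genes. The 586 others, among them all 15 chloroplast and 92 mitochondrial codes, entered no comparison. NAA20 has no symbol in that table. It was assigned to AT1G03150 from general knowledge of the gene before the data were examined.

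The comparison was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on the values as deposited, with genotype as the only term and 3 samples per group. The test was two-sided, p-values were adjusted by Benjamini-Hochberg over the 27241 genes, and a gene was called at an adjusted p under 0.05. A further count took a difference of at least 1 on the log2 scale, a 2-fold change. Errors of differences are the moderated standard errors of the fit.

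The genes named were chosen by a rule set before the data were examined. It took NAA20 and NAA25, the 12 called genes with the largest difference in each direction whose groups did not overlap, and, in each gene list, up to 4 called members with the smallest p. Where fewer than 2 members of a list were called, the 2 with the smallest p were given as values. Members that passed only when adjusted over a list alone, and the genes of the closing part, were named after their values were seen.

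The 22 gene lists, also set before the data were examined, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. The lists covered defence (pattern-triggered immunity and camalexin, NLR immune receptors, salicylic acid and systemic acquired resistance, jasmonate and ethylene defence, glucosinolate synthesis, oxidative stress and glutathione transferases), stress and protein turnover (abscisic acid, osmotic and salt response, endoplasmic reticulum protein folding, cytosolic heat shock, proteasome subunits, cytosolic ribosomal proteins, N-terminal acetylation and methionine removal), and growth and metabolism (photosynthesis, cell cycle and DNA replication, cell expansion and auxin response, flavonoid and anthocyanin synthesis, sulfate uptake and assimilation, flowering time and leaf polarity, morning and evening clock genes, senescence). Root tissue markers served as a check on the tissue sampled.

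The procedure was tested on simulated data for the 27241 genes, 3 samples against 3, with 50 genes changed at each size. It recovered 24% of the genes changed by 0.5 on the log2 scale, 60% at 1, 88% at 1.5 and 96% at 2, and 5 of its 139 calls were false. A simulated list of 20 genes moved by 0.3 was called by camera (adjusted p = 6.21e-17) and with an estimated correlation (adjusted p = 0.0143), and 0 of 20 unmoved lists were called. The simulated genes varied independently of each other. The simulation therefore gives no rate of false calls for lists whose members vary together, such as flavonoid and anthocyanin synthesis (estimated correlation 0.598).

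The alternatives were a repeated quantile normalization, centring of each array on its median, removal of the dimmest 40% of probe sets, eBayes with a variance trend and robust fit, all probe sets kept in the adjustment, the replicate number as a block, and each sample left out in turn.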

Results

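Transcript levels were measured on 6 arrays of Arabidopsis thaliana seedlings aged 17 days, 3 of the accession Col-0 and 3 of the mutant naa20-1, which per the series' design text is depleted of the catalytic subunit of NatB. NatB is an enzyme complex that acetylates the N-terminus of many proteins, with NAA20 as the catalytic and NAA25 as the auxiliary subunit. Values are log2 expression after RMA, ± SD over 3 arrays per group unless an SE is named, and each difference is naa20-1 minus Col-0. The number of arrays limits the precision of every value. Nothing in the labels states that the 3 samples of a group came from separate cultures, so the p-values of single genes measure only the spread between these samples, which may be technical. The p-values of gene lists and families from camera at a preset correlation rest mainly on the spread between genes. A small one therefore does not speak for new samples. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over the 27241 genes tested, and a gene was called at an adjusted p under 0.05.

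NAA20 (AT1G03150) was lower in all 3 naa20-1 samples. It stood at 8.79, 8.75 and 8.72 in the Col-0 samples (8.75 ± 0.04) and at 8.10, 7.60 and 7.36 in the naa20-1 samples (7.68 ± 0.38). The log2 difference was -1.07 (SE 0.18, adjusted p = 0.0407). NAA25 was at 8.37 ± 0.03 in Col-0 and 8.46 ± 0.03 in naa20-1, a difference of 0.09 that did not pass the test (SE 0.08, adjusted p = 0.669). How the allele changes the gene, and where the probe set lies in it, are not given in the sources used here, so the remaining signal says nothing of the amount of protein. The NAA20 call was close to the threshold: it held without naa20-1 replicate 1 (adjusted p = 0.0181), and leaving out any other single sample gave adjusted p-values from 0.0770 to 0.135 with the difference still below 0.

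The comparison of naa20-1 with Col-0 asked which transcripts differ in seedlings that the design text describes as depleted of the catalytic subunit of NatB. In naa20-1, 104 genes were higher and 209 were lower, of which 31 were at least 2-fold higher and 91 at least 2-fold lower. The 313 called genes were 1.15% of those tested and included 303 protein-coding genes. In all 313 the 3 values of one group lay entirely above those of the other, as they did in 5731 of all tested genes (21.0%, where chance gives 10%). Without naa20-1 replicate 3, which had the lowest mean correlation with its own group (0.993), 63 genes were higher and 134 lower, without replicate 1 these counts were 53 and 120, without replicate 2 they were 32 and 80, and leaving out a Col-0 sample left 11 to 24 higher and 51 to 70 lower. With a variance trend and robust fit, 311 genes were higher and 486 lower.

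The largest rise was in CRA1, a seed storage globulin of the cruciferin family, which went from 5.23 ± 0.42 to 8.30 ± 0.75 (8.41-fold, log2 3.07, SE 0.37, adjusted p = 0.0150). M17, a late embryogenesis abundant protein gene, rose by 1.97 (SE 0.28, adjusted p = 0.0252), and AT2G28490, which encodes a protein of the cupin group that also holds seed storage globulins, rose by 1.55 (SE 0.15, adjusted p = 0.00621). ICL, isocitrate lyase of the glyoxylate cycle, rose 4.55-fold from 5.18 ± 0.70 to 7.36 ± 0.19 (adjusted p = 0.0262). The non-coding RNA AT1G67105 rose from 7.21 ± 0.34 to 9.66 ± 0.09, a 5.44-fold difference (adjusted p = 0.00246). Among the other genes with the largest rises were UMAMIT26, of a family of amino acid transporters (log2 1.85, SE 0.16), and BGLU28, a β-glucosidase known to rise under sulfur shortage (1.78, SE 0.25). The heat shock factor gene HSFA6A (1.45, SE 0.17), the microRNA precursor MIR156f (1.43, SE 0.23), AtCDC48B of the AAA ATPase family (1.36, SE 0.22), AT1G77960 (1.60, SE 0.23) and AT1G23390 (1.41, SE 0.23) completed the 12 largest. The Col-0 values of UMAMIT26 (3.35), AT1G77960 (3.37), AT2G28490 (3.37) and MIR156f (2.82) lay under the 25th percentile of the table, 3.72, and may be background, so the size and the rank of these rises are uncertain. Seed storage globulin genes resemble each other in sequence, so the signal of CRA1 may include that of close relatives.

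The genes that fell furthest were AT5G38910, a germin-like protein gene, and IGMT2, an indole glucosinolate O-methyltransferase gene. AT5G38910 fell from 8.61 ± 0.30 to 5.49 ± 0.28 (8.71-fold lower, adjusted p = 0.00227) and IGMT2 from 5.90 ± 0.22 to 2.88 ± 0.31 (adjusted p = 0.00227). AT5G42530 fell from 11.03 ± 0.23 to 8.09 ± 0.41 (7.66-fold lower, adjusted p = 0.00277). CCOAMT, of the caffeoyl-CoA O-methyltransferase family, had a log2 difference of -2.60 (SE 0.21, adjusted p = 0.00404), the glutathione transferase gene GSTF7 also of -2.60 (SE 0.19, adjusted p = 0.00277), and ACD6, an ankyrin-repeat protein that promotes salicylic acid signalling, of -2.50 (SE 0.21, adjusted p = 0.00404). CYP81F2, a cytochrome P450 that modifies indole glucosinolates, was 4.19-fold lower (log2 -2.07, SE 0.23, adjusted p = 0.0115), and the cysteine-rich receptor-like kinase gene CRK41 was 3.89-fold lower (log2 -1.96, SE 0.24, adjusted p = 0.0167). The remaining genes of the 12 largest falls were the non-coding RNA AT4G04223 (-2.40, SE 0.22), MRD1 (-2.10, SE 0.17), AT5G44585 (-1.99, SE 0.18) and AT1G58320 (-1.98, SE 0.17). The naa20-1 values of IGMT2 (2.88), CCOAMT (3.28) and MRD1 (3.44) lay under the 25th percentile of the table, 3.72, and may be background, so the size and the rank of these falls are uncertain. IGMT2 belongs to a cluster of near-identical methyltransferase genes and GSTF7 has the near-identical copy GSTF6, so the values of these genes are uncertain as to which copy they measure.

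**Figure D1:**
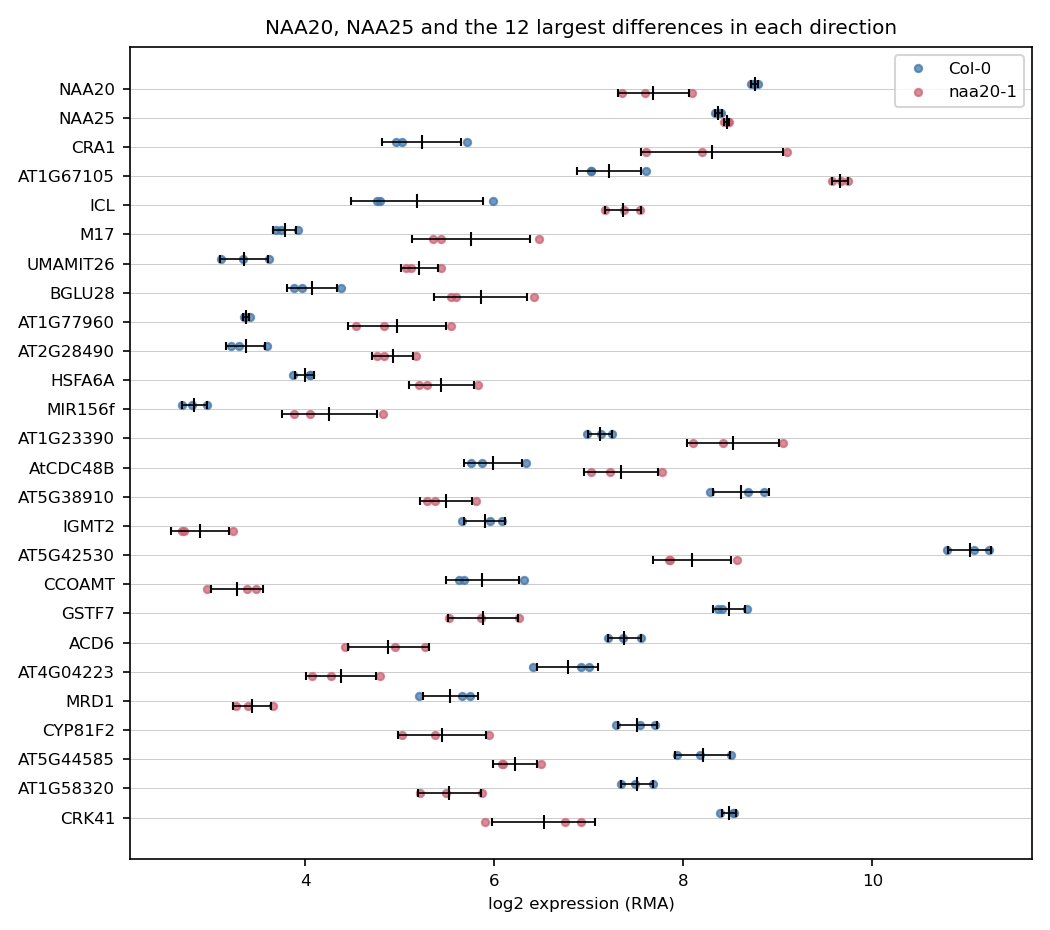
Log2 expression of NAA20, NAA25 and the 12 genes with the largest called differences in each direction, with 1 point per array, a vertical tick at each group mean and bars of 1 SD (n = 3 per group, Col-0 blue, naa20-1 red). For NAA20 the Col-0 points lie at 8.72 to 8.79 and the naa20-1 points at 7.36 to 8.10, and for NAA25 the group means differ by 0.09.

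The 22 gene lists held 407 genes and were fixed before the data were examined. Tested with limma's camera against all other genes (correlation preset at 0.01, Benjamini-Hochberg over the lists), 11 lists were called, 3 higher and 8 lower in naa20-1. With a correlation estimated from the data, 1 of the 11, pattern-triggered immunity and camalexin, was still called. The estimate was -0.009 for that list and 0.006 for NLR receptors, under the preset. A higher correlation therefore does not account for the larger adjusted p-values of these lists. The simulated list of independent genes also had a larger one with an estimate. With an estimate, camera tests on the residual degrees of freedom of the fit, here 4, and with a preset on far more. A call lost with an estimate is therefore no sign by itself that the members of a list vary together. The other called lists had estimates above the preset, from 0.014 for proteasome and cell expansion up to 0.598 for flavonoid synthesis. Root tissue markers were among the 8 lower lists (12 of 19 differences negative, 7 positive, camera adjusted p = 0.0320, adjusted p = 0.454 with an estimated correlation). The lower lists of defence, growth, photosynthesis and glucosinolate synthesis thus moved the same way as most markers of another tissue. The fry test, which asks whether the genes of a list move one way on balance without comparing them with other genes, called 6 lists.

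Genes of pattern-triggered immunity and camalexin synthesis were lower as a list. Of 19 members, 7 fell, 0 rose and 12 did not pass the test, 17 of the 19 differences were negative, and adjusted over the list alone 9 fell. NHL10, a gene induced by bacterial flagellin, fell from 6.69 ± 0.14 to 5.62 ± 0.02 (log2 -1.07, SE 0.10, adjusted p = 0.00560), and PEN3, a transporter of indole compounds, fell from 10.41 ± 0.01 to 9.39 ± 0.22 (2.03-fold lower, adjusted p = 0.0138). CYP81F2 and CYP71A12, the latter a P450 of camalexin-related indole metabolism, were also among the 7 (CYP71A12 log2 -0.94, SE 0.13, adjusted p = 0.0224). CYP71A12 and CYP71A13 are near-identical copies, and the signal of CYP71A12, at 2.97 ± 0.22 in Col-0 and 2.04 ± 0.10 in naa20-1, lay under the 25th percentile of the table (3.72). The median log2 difference of the list was -0.28 (camera adjusted p = 4.79e-11, adjusted p = 0.0348 with an estimated correlation), and its mean was lower by 0.51 to 0.59 in each of the 3 naa20-1 samples. Root tissue markers were lower as well (mean -0.20, median -0.07, 7 of 19 lower when adjusted over the list alone, camera adjusted p = 0.0320, adjusted p = 0.454 with an estimated correlation).

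Genes of NLR immune receptors, which recognise pathogen effectors inside the cell, were lower as a list. Of 17 members, 1 fell (RPP4, 10.21 ± 0.23 to 9.41 ± 0.15, adjusted p = 0.0497), 16 did not pass the test and 16 of the 17 differences were negative. Adjusted over the list alone 7 fell. RPS4 had a difference of -0.70 (SE 0.13) at an adjusted p of 0.0562. The median log2 difference was -0.27 (camera adjusted p = 1.45e-06, adjusted p = 0.0614 with an estimated correlation). RPP4 lies in a cluster of near-identical receptor genes and is uncertain for that reason.

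The list of salicylic acid and systemic acquired resistance was lower (camera adjusted p = 0.00487, adjusted p = 0.245 with an estimated correlation). Of 24 members, 2 fell and 22 did not pass the test, and adjusted over the list alone 6 fell. FMO1, which makes the mobile signal N-hydroxypipecolic acid, was 2.23-fold lower (5.14 ± 0.24 to 3.99 ± 0.22, adjusted p = 0.0225). CBP60G, a transcription factor of salicylic acid synthesis, was 2.44-fold lower (6.89 ± 0.17 to 5.60 ± 0.38, adjusted p = 0.0289). The median difference of the list was -0.06, and the list was not called when dim probe sets were left out (adjusted p = 0.240).

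The list of jasmonate and ethylene defence was also lower (camera adjusted p = 0.000257, adjusted p = 0.255 with an estimated correlation), with 4 of 24 members called lower, 20 not called and 8 lower when adjusted over the list alone. The lipoxygenase genes LOX4 (8.81 ± 0.11 to 7.18 ± 0.09, adjusted p = 0.00227) and LOX3 (9.19 ± 0.10 to 8.47 ± 0.08, adjusted p = 0.0193) fell 3.09-fold and 1.65-fold. VSP1, a vegetative storage protein gene responsive to jasmonate, fell 2.16-fold (adjusted p = 0.00404), and PR4 fell 1.45-fold (adjusted p = 0.0459). The median difference was -0.11.

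Proteasome subunit genes were higher as a list. None of the 12 members passed the test over all genes, 7 were at an unadjusted p under 0.05 in limma, 7 were higher when adjusted over the list alone, and 11 of 12 differences were positive. PBA1 was at 9.53 ± 0.07 in Col-0 and 9.95 ± 0.04 in naa20-1 (log2 0.42, SE 0.08, adjusted p = 0.0726), and RPT2A at 7.54 ± 0.12 and 8.01 ± 0.13 (log2 0.46, SE 0.11, adjusted p = 0.113). The median difference was 0.23 (camera adjusted p = 3.35e-05, adjusted p = 0.0792 with an estimated correlation), and the list mean was higher by 0.20 to 0.23 in each of the 3 naa20-1 samples.

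Genes of cell expansion and auxin response were lower as a list, with 0 of 18 members called, 7 at an unadjusted p under 0.05 and 4 lower when adjusted over the list alone. XTH4, of the cell wall xyloglucan transferases, differed by -0.42 (SE 0.09, adjusted p = 0.0886) and GH3.3, of the enzymes that conjugate auxin, by -0.76 (SE 0.17, adjusted p = 0.106). The median difference was -0.20 (camera adjusted p = 0.000339, adjusted p = 0.100 with an estimated correlation). The root tissue markers, which moved the same way, had a mean of -0.20 (camera adjusted p = 0.0320, adjusted p = 0.454 with an estimated correlation). Nuclear genes of photosynthesis were lower by a small median of -0.09 (camera adjusted p = 0.00487, adjusted p = 0.276 with an estimated correlation), with 0 of 27 members called, 1 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. LHCB1.3 differed by -0.22 (SE 0.08, adjusted p = 0.268) and LHCA2 by -0.15 (SE 0.08, adjusted p = 0.456). The LHCB1 genes are near-identical copies. The fry test did not call the photosynthesis list (adjusted p = 0.0517).

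Genes of flavonoid and anthocyanin synthesis were higher as a list in the 3-against-3 comparison (median 0.37, camera adjusted p = 0.00487, adjusted p = 0.633 with an estimated correlation), and naa20-1 replicate 3 decided this. The list mean differed from that of Col-0 by -0.08, 0.15 and 1.01 in naa20-1 replicates 1, 2 and 3, and without replicate 3 the list was not called (adjusted p = 0.753). None of its 22 members was called, 3 were at an unadjusted p under 0.05 and 0 when adjusted over the list alone. F3'H, a flavonoid hydroxylase, differed by 0.58 (SE 0.15, adjusted p = 0.129) and 5MAT, an anthocyanin malonyltransferase, by 0.70 (SE 0.26, adjusted p = 0.280).

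The title of the series names the response to osmotic stress. The growth conditions given for these samples include no osmotic or salt treatment, so the list below compares untreated levels and cannot test that response. The list of abscisic acid, osmotic and salt response was at the threshold (median 0.10, camera adjusted p = 0.0497, adjusted p = 0.659 with an estimated correlation), and it too rested on naa20-1 replicate 3. Its mean differed from that of Col-0 by -0.02, 0.01 and 0.40 in replicates 1, 2 and 3, and without replicate 3 its direction turned to lower (adjusted p = 0.753). Leaving out Col-0 replicate 2 gave an adjusted p of 0.176, the fry test gave 0.613, and with all probe sets kept in the test it was 0.0507. None of its 32 members was called, 6 were at an unadjusted p under 0.05 and 2 were higher when adjusted over the list alone. These were RAB18, a dehydrin gene, at 6.54 ± 0.26 in Col-0 and 7.69 ± 0.50 in naa20-1 (log2 1.15, SE 0.25, adjusted p = 0.0921), and RD29B at 7.15 ± 0.31 and 8.23 ± 0.47 (log2 1.08, SE 0.25, adjusted p = 0.110). Both were higher in all 3 naa20-1 samples.

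Genes of glucosinolate synthesis were lower as a list although the only called member rose. MAM3, which elongates the chain of aliphatic glucosinolates, rose 2.17-fold (log2 1.12, SE 0.11, adjusted p = 0.00648). The other 21 of 22 members did not pass the test, and MYB34, a regulator of indole glucosinolates, differed by -0.43 (SE 0.09, adjusted p = 0.0863). Adjusted over the list alone, MAM3 and CYP79F2 were higher and 5 members lower. The median difference was -0.15 (camera adjusted p = 0.0127, adjusted p = 0.633 with an estimated correlation). The list mean differed from that of Col-0 by -0.24, -0.18 and 0.08 in naa20-1 replicates 1, 2 and 3. Replicate 3 thus went the other way, and without it the camera adjusted p was 3.07e-05. The call was lost without naa20-1 replicate 1 (adjusted p = 0.210), naa20-1 replicate 2 (0.0686) or Col-0 replicate 3 (0.0556), in the fry test (0.506) and without dim probe sets (0.0597).

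Markers of root tissue were lower as a list, with 0 of 19 members called, 9 at an unadjusted p under 0.05 and 7 lower when adjusted over the list alone. The 7 were CASP1 to CASP5, membrane proteins of the endodermal Casparian strip, the tonoplast aquaporin TIP2;3 and the cell wall protein gene PRP3. TIP2;3 was at 10.27 ± 0.06 in Col-0 and 9.58 ± 0.22 in naa20-1, with an adjusted p just above 0.05, and CASP4 differed by -0.59 (SE 0.13, adjusted p = 0.102). The median difference was -0.07 (camera adjusted p = 0.0320, adjusted p = 0.454 with an estimated correlation). The call was lost without naa20-1 replicate 3 (adjusted p = 0.0641), Col-0 replicate 2 (0.0916) or Col-0 replicate 3 (0.0632), in the fry test (0.123) and without dim probe sets (0.0597).

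**Figure D2:**
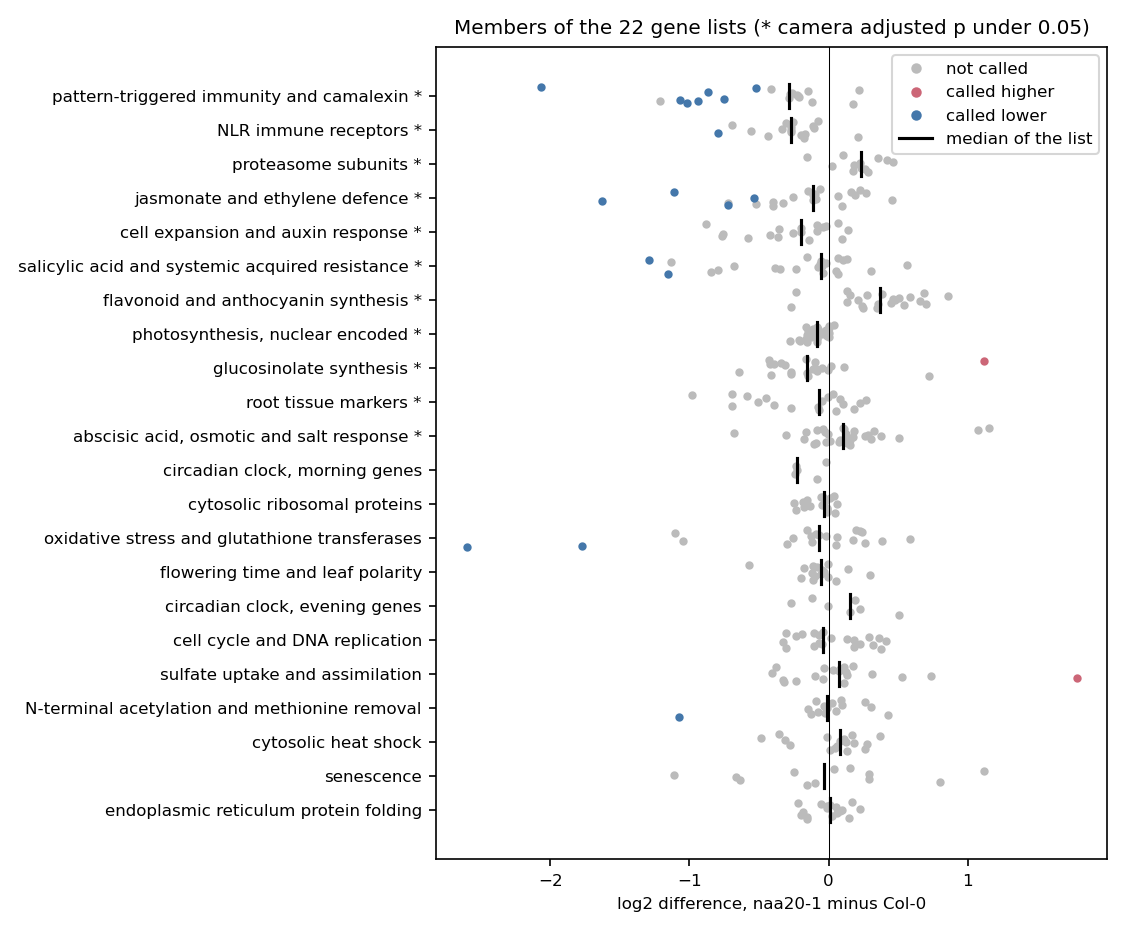
Log2 differences (naa20-1 minus Col-0, 3 arrays each) of the members of the 22 gene lists, with 1 point per gene, coloured where the gene was called higher or lower, and a black tick at the median of each list. Asterisks mark the 11 lists called by camera, with medians from -0.28 for pattern-triggered immunity and camalexin to 0.37 for flavonoid and anthocyanin synthesis.

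**Figure D3:**
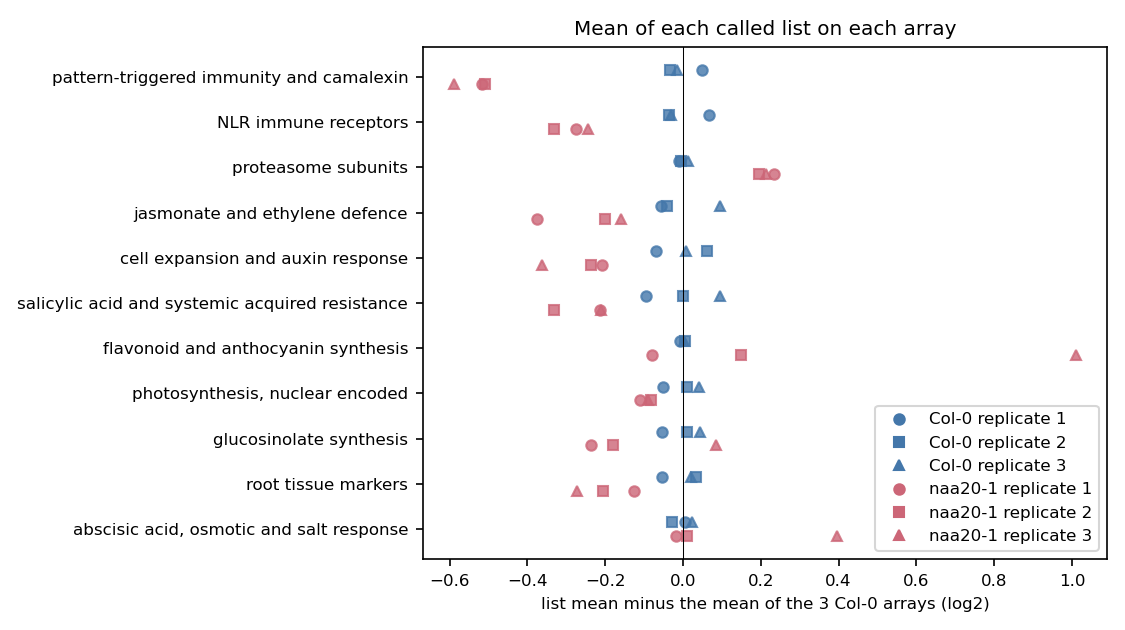
Mean log2 level of each of the 11 called lists on each of the 6 arrays, as the difference from the mean of the 3 Col-0 arrays (Col-0 blue, naa20-1 red, marker shape by replicate). For pattern-triggered immunity the 3 naa20-1 arrays lie between -0.59 and -0.51, and for flavonoid synthesis they lie at -0.08, 0.15 and 1.01.

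The other 11 lists were not called. The list of oxidative stress and glutathione transferases (camera adjusted p = 0.164) held 2 members that fell, GSTF7 and GSTF6 (log2 -1.77, SE 0.21, adjusted p = 0.0149), with 3 of 21 lower when adjusted over the list alone. The list of sulfate uptake and assimilation (adjusted p = 0.712) held 1 called member of 20, BGLU28, which was also the only one when adjusted over the list alone, and the transporter gene SULTR4;2 differed by 0.53 (SE 0.15, adjusted p = 0.161). In the list of N-terminal acetylation and methionine removal (adjusted p = 0.875) NAA20 was the only called member of 15. Adjusted over the list alone, NAA20 was lower and MAP1B, a methionine aminopeptidase gene, was higher (log2 0.43, SE 0.11, adjusted p = 0.147 over all genes). The median (-0.01) and mean (-0.02) of this list were below 0 while the camera test pointed upward. The senescence list (adjusted p = 0.948) had 0 of 12 members called and 6 at an unadjusted p under 0.05. Adjusted over the list alone, NAP (0.80, adjusted p = 0.0845 over all genes) and PAO (0.29, adjusted p = 0.185) were higher and SAG13 and SAG21 lower, and the median of -0.03 and mean of -0.02 again stood against an upward test.

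In the remaining lists none of the members was called, over all genes or adjusted over the list alone. The morning clock list (camera adjusted p = 0.119, 0 of 5 at an unadjusted p under 0.05) included CCA1 at -0.23 and PRR9 at -0.24, and the evening clock list (0.434, 2 of 7) included ELF4 at 0.22 and PRR5 at -0.27. Cytosolic ribosomal protein genes (0.131, 2 of 19) included RPL5A at -0.25 and RPL24B at -0.19. The list of flowering time and leaf polarity (0.307, 2 of 17) included MAF4 at -0.57 and PHB at 0.30. Genes of the cell cycle and DNA replication (0.674, 5 of 21) included MCM2 at 0.32 and PCNA2 at 0.41, with a median of -0.04 against a mean of 0.03 and an upward test. Genes of the cytosolic heat shock response (0.948, 3 of 17) included HSFB2A at -0.36 and MBF1C at -0.28, and genes of protein folding in the endoplasmic reticulum (0.948, 0 of 17) included BZIP60 at -0.20 and IRE1A at -0.18, with a median of 0.01 against a mean of -0.01 and a downward test.

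Of the 20 tested genes nearest to NAA20, 10 on each side by order along the chromosome, limma called 0, and 3 were at an unadjusted p under 0.05. Their differences ran from -0.28 to 0.52. The adjacent gene FZL, a membrane-remodelling GTPase of chloroplasts, differed by 0.44 (SE 0.09, adjusted p = 0.0689). FZL was called without dim probe sets (adjusted p = 0.0310) and with a variance trend and robust fit (adjusted p = 0.0107).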

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

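The comparison with genes of the closest locus codes was chosen after the result was seen. Among the 586 probe sets whose locus codes did not match the reference gene table, 1 was called higher in naa20-1 than in the Col-0 controls when all probe sets were tested together, which is a signal in data outside the comparison. This was AT1G75388, at 5.06 in Col-0 and 5.67 in naa20-1 (log2 0.61, SE 0.10, adjusted p = 0.0366). A further 1, AT1G68552, was called lower (log2 -0.58, SE 0.09, adjusted p = 0.0429). The genes with the closest locus codes differed the same way, bZIP44 (AT1G75390) by 0.61 (adjusted p = 0.0352) and CRF10 (AT1G68550) by -0.61 (adjusted p = 0.0344). These genes were already called in the comparison. Whether the unmatched probe sets measure anything other than the transcripts of these genes was not tested, so a separate signal is not shown.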

How the results depend on the processing

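No test in this part was chosen after the result was seen. Repeating the quantile normalization or centring the arrays left 313 genes called and 11 lists called, but the arrays already shared their distribution, so both moved almost nothing and say nothing about stability. None of the called genes changed direction under any setting. The groups of all 313 did not overlap, so leaving out a sample could not reverse one, and this does not measure stability either. Calls of single named genes were lost 86 times and gained 1 time over the fits without 1 sample. Among named genes, 5 gained a call without dim probe sets, 11 with a variance trend and robust fit, and 1 lost it with all probe sets. The mean of several probe sets per gene was not run, since each gene had 1. Leaving out each sample in turn gave 11 to 63 genes higher, 51 to 134 lower, 9 to 32 at least 2-fold higher and 42 to 73 at least 2-fold lower, with 63 to 155 of the 313 genes shared, and an NAA20 difference of -1.28 to -0.91. Without dim probe sets 430 genes were called, including all 237 of the 313 still tested, and with all probe sets 297 were, 295 of them shared. With a variance trend and robust fit 311 genes were higher and 486 lower, with 304 of the 313 shared, and without dim probe sets or with this fit 1 neighbour of NAA20, FZL, was called. Fewer tests or samples account for part of these shifts and the cause of the rest was not tested. Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, gave 313 genes, and the highest other gave 0 (848 to 1285 genes at an unadjusted p under 0.05 in the others, 3871 in the real one), but 10 splits are too few for a share under 0.05. The signal over background of each probe set is not known, so differences between dim values are the least certain.

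The samples share replicate numbers, and nothing in the labels says that these pair them. Deviations from the group means of same-numbered samples correlated across genes at 0.024, 0.062 and 0.013. These values are low, but a low correlation cannot exclude a shared batch, so pairing stays undecided. Of the 6 samples 5 correlated best with their own number in the other group, a hint from the data and not from the design, and naa20-1 replicate 3 correlated best with Col-0 replicate 1 (0.023). Of the 6 pairs with different numbers 5 were negative. Deviations sum to 0 within a group, so positive values for same numbers force some negative ones among the other pairs. With the number as a replicate block, 61 genes were higher and 129 lower, with 164 of the 313 shared, 6 named genes lost and 3 gained a call, and NAA20 differed by -1.07 at an adjusted p of 0.0542. With the numbers of the sample descriptions as the block, of which the groups share 2, 2 genes were higher and 17 lower, all at least 2-fold, and NAA20 differed by -0.91 (adjusted p = 0.146). This block took the call from 26 named genes and left 1 residual degree of freedom. The samples alone in their block, naa20-1 replicate 3 and Col-0 replicate 2, add nothing to its differences, which rest on the other samples. The first block changed no call of a list. Under the second the lists of flavonoid synthesis (adjusted p = 0.742) and root markers (0.150) lost their call, that of oxidative stress gained one (0.0160), and the lists of abscisic acid (0.652), heat shock (0.240), sulfate (0.773) and senescence (0.656) turned to lower. Leaving out naa20-1 replicate 3 alone also took the call from flavonoid synthesis and abscisic acid (camera adjusted p = 0.753 each). Their changes under the second block therefore do not show a batch.

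With an estimated correlation 10 of the 11 called lists lost their call: NLR receptors (adjusted p = 0.0614), proteasome (0.0792), cell expansion (0.100), salicylic acid (0.245), jasmonate (0.255), photosynthesis (0.276), root markers (0.454), flavonoid and glucosinolate synthesis (0.633 each) and abscisic acid (0.659). In the fry test the lists of photosynthesis (0.0517), root markers (0.123), glucosinolate (0.506) and flavonoid synthesis (0.511) and abscisic acid (0.613) lost it. Without dim probe sets salicylic acid (0.240), root markers and glucosinolate synthesis (0.0597 each) lost it, and the uncalled lists of heat shock (0.521), sulfate (0.893) and evening clock genes (0.976) turned to lower. With all probe sets abscisic acid lost it (0.0507). With the variance trend and robust fit morning clock genes gained a call (0.0462) and senescence turned to lower (0.937).

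Over the fits without 1 sample, list adjusted p-values ran from 0.00636 to 0.753 for abscisic acid, 7.60e-06 to 0.753 for flavonoid synthesis, 3.07e-05 to 0.210 for glucosinolate synthesis, 0.00503 to 0.0916 for root markers and 0.0481 to 0.374 for morning clock genes. Among uncalled lists that turned in some of these fits, they ran from 0.629 to 0.912 for N-terminal acetylation, 0.493 to 0.926 for protein folding, 0.502 to 0.901 for heat shock, 0.359 to 0.907 for the cell cycle, 0.0706 to 0.821 for sulfate and 0.753 to 0.926 for senescence. The lists of pattern-triggered immunity (highest 3.33e-09), NLR receptors, proteasome, jasmonate, salicylic acid, cell expansion and photosynthesis (highest 0.0448) were called in all 6 of these fits. These fits used camera at the preset correlation only. Of the lists just named, pattern-triggered immunity alone was also called with an estimated correlation on all 6 arrays.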

Other observations

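The seed and reserve lists, the families and the tests of root share, time of day and neighbour placement in this part were chosen after the result was seen, and the seed and young-seedling tests were set after the largest differences, but before the values they measure, were seen. Of 20 genes of seed reserves and late seed maturation, a list written after the largest differences were seen, 5 were called, all higher in naa20-1, and 15 were not, with differences from -0.13 to 0.77. Beside CRA1 and M17 the called genes were CRU3, SESA3 and SESA4, and no test of the list as a whole was made. CRU3, a further cruciferin gene, rose from 5.49 ± 0.06 to 6.74 ± 0.25 (2.38-fold, adjusted p = 0.00918, n = 3 per group), and the albumin genes SESA3 (log2 0.85, SE 0.10, adjusted p = 0.0129) and SESA4 (0.67, SE 0.11, adjusted p = 0.0458) rose. OLEO1, an oleosin of oil bodies, differed by 0.77 (SE 0.14, adjusted p = 0.0519), and SESA1, SESA2, SESA5 and CRB by 0.18, -0.13, 0.18 and 0.24, with none of these called. The regulators of seed maturation ABI3, FUS3 and LEC1 differed by 0.39, -0.02 and 0.00 and were not called. SESA1 to SESA4 are similar copies in tandem and are uncertain as single genes.

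Families of genes sharing a symbol stem gave a further view. Of 178 families with at least 10 tested genes, camera called 8, all lower in naa20-1. The SAUR family of auxin-induced growth genes was first (16 genes, median -0.58, adjusted p = 8.26e-06), but with an estimated correlation neither it nor any other family was called by limma's camera (0 of 178, lowest adjusted p = 0.769, the value of SAUR too), and 7 were at an unadjusted p under 0.05. The estimated correlation of SAUR was 0.003, under the preset of 0.01, so a higher correlation does not account for its lost call. With an estimate the test rests on 4 residual degrees of freedom and is adjusted over 178 families. It could hardly call any family, so the lost calls are no evidence against them. The called SAUR genes were SAUR28 (-1.23), SAUR63 (-0.81), SAUR68 (-0.80) and SAUR24 (-0.73), all lower. At the preset correlation the receptor-like protein family RLP (52 genes, median -0.15, adjusted p = 0.000111) held 3 called genes, the transcription factor family WRKY (67 genes, median -0.07, adjusted p = 0.0121) held WRKY53 (-0.87), WRKY33 (-0.75) and WRKY18 (-0.69), and the receptor-like kinase family CRK (42 genes, median -0.10, adjusted p = 0.0125) held CRK41, CRK10 and CRK25. The others were AGP, ACA, ERF and CRF, with adjusted p-values of 0.00120, 0.009998, 0.0121 and 0.0362. SAUR genes are short and similar in sequence, so single members are uncertain. The 8 MIR156 precursors, looked at after MIR156f was seen and not tested as a group, had positive differences from 0.08 to 1.43 with MIR156f the only called one, but 5 of them, MIR156f included, lay under the 25th percentile in Col-0 and may be background there. The adjacent AT5G26146 rose by 1.34 (SE 0.13, adjusted p = 0.00617). The proteasome gene RPT5B (0.52, adjusted p = 0.0474), AtCDC48B (1.36) and the transcription factor gene NAC103 (1.01, adjusted p = 0.0167) rose as well.

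The rise of CRA1, CRU3 and M17 was weighed against RNA of whole seeds and against a younger state of the seedlings. Whole seeds would bring their other abundant mRNAs, yet 10 of these had a median difference of 0.21 (bootstrap 95% interval over genes 0.05 to 0.67), which met the bound set beforehand and argues against seeds as the only cause of rises of 1.25 to 3.07. These 10 were the genes left once the risen CRA1, CRU3 and M17 had been set apart, which favours a low median. The interval is over genes, some of them similar copies, and not over samples. A member of the 10, AT1G03890 (-0.09), was entered as CRU2, a name that the reference table does not give to that locus. The 5 of the 10 that were not under the 25th percentile of 3.72 in Col-0, taken alone after the values were seen, had a median of 0.24 (-0.09 to 0.77), and since SESA3 and SESA4 rose, a small contribution of seeds stays open. A younger state, a candidate biological explanation, was tested on 8 genes of reserve mobilisation other than ICL, with a median difference of 0.19 (0.06 to 0.24), which met its bound set beforehand by less than the width of the interval. That bound was set aside after the values were seen, because 6 of the 8 genes lay above the 75th percentile of 8.12 in Col-0, where a small share of younger tissue would be hidden, while MLS and SDP1 (6.15 and 7.70 in Col-0) differed by 0.45 (adjusted p = 0.138) and -0.06 (adjusted p = 0.875), so a younger state stays open, as does a direct effect of the genotype, which was not tested.

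The lower level of the pattern-triggered immunity list was weighed against a smaller share of root RNA and against a different time of sampling. The median of the root markers lay 0.22 above that of the immunity list, with a bootstrap 95% interval over genes of -0.17 to 0.81 that includes 0, so a smaller root share may contribute. A smaller root share alone would not lower genes of green tissue, yet 22 of 27 photosynthesis genes were negative and 5 positive. That shift was small (median -0.09) and was not called by the fry test. Limma called 0 of the 12 clock genes and 2 were at an unadjusted p under 0.05, but the farthest bound of their 95% intervals lay at 1.12, beyond the bound of 1 set for this test after a first form of it had been seen. Neither explanation can be told apart from an effect of the genotype, because the intervals are too wide to decide.

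Called genes lay next to each other more often than placed at random. There were 10 pairs of neighbouring genes called in the same direction, 5 higher and 5 lower, against a mean of 1.99 and a highest of 9 in 10000 random placements (one-sided permutation p = 1e-04, the smallest they can give), which argues against chance placement. The pairs were AT1G02610 with AT1G02620, GSTF7 with GSTF6, AT1G36622 with AT1G36640, MRD1 with HEI10, AT2G41250 with M17, AT4G26288 with AT4G26290, SESA3 with SESA4, AT5G26146 with MIR156f, AT5G41740 with AT5G41750, and AT5G48530 with AT5G48540. Some are tandem copies or overlapping features that may share probe signal, and this, like joint regulation of neighbours, was not tested.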
